A study of Homo sapiens with 8 samples.

How the data were processed

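The data were H3K27me3 ChIP-seq libraries of 2 human lymphoma B-cell lines, LY19WT and LY19Y646F, each with 3 ChIP replicates and 1 input. The files analysed were 2 lists of H3K27me3 islands, 1 per line. Per the submitters' processing notes, Bowtie2 2.2.9, SAMtools 1.3.1, SICER and bedtools were used with genome build hg19, and the versions of SICER and bedtools were not given in the sources used here. Per the labels, the islands of a line were called by SICER on merged replicates against the input of the same line at an FDR of 0.001. SICER joins enriched windows across short gaps into islands, which suits a broad mark. In both lists island starts and widths were multiples of 200 bp and the smallest gap between islands was 800 bp.

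Per the file headers, each island has a count of ChIP reads, a count of input reads, a fold, a p-value and an FDR. The deposited counts are raw reads inside the island. The deposited fold is a linear ratio, the ChIP count over the input count divided by 1 constant per list, 3.07 in LY19WT and 2.62 in LY19Y646F, which was recovered from the values and read as the ratio of the library sizes. The deposited p-value equalled a Poisson tail probability of the ChIP count given the scaled input count in 100% of the 54354 LY19WT and 47275 LY19Y646F islands checked, within 0.01 on the log10 scale. Fold, p-value and FDR are the authors' own values and were used to describe, rank or filter islands within a list. Because replicates were merged before calling, no value has a replicate error, and no p-value between the lines was computed. Because the p-value is computed on raw reads, it depends on sequencing depth and DNA abundance as well as on enrichment. The number of tests implied by FDR, p-value and rank ran from 59597 to 60293 in LY19WT and from 49660 to 50007 in LY19Y646F. A complete ranking would give about 1 value per list, so the lists analysed here may lack a small number of islands.

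Covered length, width and coverage per chromosome were computed from the coordinates, which are given here as 1-based hg19 positions. Chromosome spans ran from the first to the last island of either list. Overlap was computed with bedtools 2.31.1 at a minimum of 1 bp. It was set beside 100 seeded placements of each LY19Y646F island at random on its chromosome, and beside 100 rotations of all LY19Y646F islands of a chromosome by 1 random offset, the latter chosen after seeing the data. The Jaccard index is the shared length over the length covered in either line. Coverage was compared in windows of 100 kb. Paired islands overlapped by at least 50% of both, and their levels were compared after scaling by input reads and the library ratio, by total ChIP reads in islands or by input reads alone. Input density is the number of input reads per kb of an island. Its median over 10 Mb bins with at least 5 islands, relative to the autosomal median of the line, was read as a relative measure of DNA abundance. Bins within 15% of that median in both lines are called normal. The input density of an island depends also on mappability and library composition.

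Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The steps were tested on simulated lists built from 57854 LY19WT islands. A planted Jaccard index of 0.498 was recovered as 0.498, and copy ratios planted on chromosomes 4 and 20 were recovered to within 0.0054.

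Groups, comparisons, alternatives and the rule for named regions were set before the data were examined. The rule named the 5 longest islands of each line and the 5 windows with the largest difference in coverage in each direction, joined with neighbouring windows. Chromosomes were described after their values were seen. Alternatives were FDR limits of 1e-05 and 1e-10, joining islands across gaps of up to 5 kb, and autosomes alone. Others were overlap of 50% of 1 or both islands, lists of equal covered length, windows of 50 and 500 kb, and the other scalings. For equal length, the LY19WT list was cut by p-value and then fold to the covered length of LY19Y646F. Bins of normal input and the removal of islands with input over 3 times the median were added after seeing the data. Promoter, gene list and gene body comparisons had been planned, but the gene table at hand was on GRCh38.p14 and the islands on hg19. Positions were not converted, and genes were not analysed here.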

Results

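H3K27me3, the repressive histone mark written by the EZH2 methyltransferase of Polycomb repressive complex 2, was profiled by ChIP-seq in 2 human B-cell lymphoma lines. LY19WT carried wild-type EZH2. LY19Y646F expressed EZH2-Y646F, a mutant of the catalytic SET domain that recurs in B-cell lymphoma, constitutively from a CMV promoter. Each line was represented by 3 ChIP libraries and 1 input library. The comparison asked how the H3K27me3 landscape differed between the lines. The ChIP libraries of a line had been merged before enriched islands were called, which gave 1 island list per line. The values below therefore describe 2 lists with no spread between replicates and no test between the lines. Islands of LY19WT held 37556030 ChIP reads and 4949411 input reads, and those of LY19Y646F held 17410034 and 3527109. Total library sizes were not given in the sources used here. Scaled to the median input density over autosomal islands, 8.41 reads per kb in LY19WT and 8.42 in LY19Y646F, the merged ChIP library of LY19WT was 1.17 times as deep.

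H3K27me3 islands were fewer and covered less of the genome in LY19Y646F than in LY19WT. LY19WT had 58144 islands over 554.6 Mb, and LY19Y646F had 47432 islands over 383.6 Mb, ratios of 0.816 and 0.692. The counts refer to the lists as analysed here, which may lack a small number of islands. These lengths were 18.7% and 12.9% of the genome span covered by the lists. The median island measured 5.8 kb in each line, with quartiles of 3.6 and 10.6 kb in LY19WT and of 4.2 and 9.2 kb in LY19Y646F. The lists parted among the broadest domains. LY19WT had 893 islands wider than 50 kb, which made up 12.6% of its covered length, against 214 islands and 4.19% in LY19Y646F. By the estimate above, the merged LY19WT ChIP library was 1.17 times as deep, and without reads the depths could not be made equal. ChIP reads in islands differed more, at 0.464 times in LY19Y646F, a total that also falls with a shorter list. Variation between ChIP preparations could also change the number and width of islands and was not tested.

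**Figure D1:**
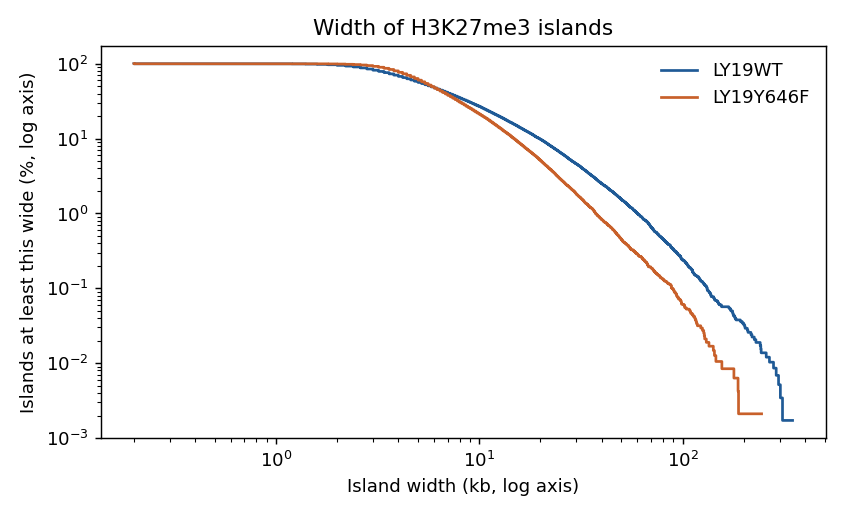
Share of islands (percent, log axis) at least as wide as the width on the horizontal axis (kb, log axis), with 1 curve per line. The curves cross near the shared median of 5.8 kb, and LY19WT lies above LY19Y646F among broad islands, up to maxima of 347.4 and 244.6 kb.

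The broadest LY19WT domains lay on chromosomes 12, 8 and 6. The longest island ran from 2556201 to 2903600 on chromosome 12 (hg19), with 47144 ChIP and 4334 input reads and an authors' fold of 3.54. LY19Y646F islands covered 87.6% of it. The next ran from 2245401 to 2555400 on the same chromosome arm and was covered to 49.9% in LY19Y646F, and the fifth, from 5252801 to 5541400, to 45.7%. The island from 123349201 to 123651800 on chromosome 8 was covered to 29.7% in LY19Y646F, and that from 91298401 to 91594800 on chromosome 6 to 31.2%. Input density of LY19WT was above its autosomal median around the chromosome 12 and chromosome 8 islands, at 1.3 and 1.52 times, and 0.925 times around the chromosome 6 island.

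The broadest LY19Y646F domains clustered near the start of chromosome 6. The longest, from 6687601 to 6932200, spanned 244.6 kb with 14998 ChIP and 2866 input reads and an authors' fold of 2.0, and LY19WT islands covered 1.64% of it. The next, from 2575001 to 2763400, was covered to 10.6% in LY19WT, and the one from 3556601 to 3744000 to 80.1%. Input density of LY19Y646F in this part of chromosome 6 was 1.47 times its autosomal median. Broad islands present in both lines lay on chromosome 5 from 11027801 to 11206600, covered to 88.7% in LY19WT, and on chromosome 20 from 55501201 to 55657200, covered to 86.0%.

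The difference in coverage was uneven across chromosomes. Covered length was lower in LY19Y646F on 17 of 22 autosomes and higher on chromosomes 17, 19, 20, 21 and 22. Chromosome 4 had 2454 islands in LY19WT and 359 in LY19Y646F, covering 9.47% and 1.21% of its span. Coverage of chromosome 14 was 16.7% and 3.25%, and that of chromosome 15 was 22.1% and 4.27%. The median input density of LY19Y646F on these chromosomes was 0.826, 0.767 and 0.751 times that on its other autosomes. From 150 to 170 Mb of chromosome 4, LY19Y646F had 41 islands against 400 in LY19WT. This part was chosen after seeing the data for normal input in both lines and at least 0.95 in LY19Y646F. Chromosome 13, covered to 17.3% in LY19WT and 8.69% in LY19Y646F, had an input density 1.41 times that of the other autosomes in LY19WT. Parts of chromosomes 16 and 18 were also sparse in LY19Y646F. From 40 to 70 Mb of chromosome 16 it had 129 islands against 487 in LY19WT. From 0 to 10 and 10 to 20 Mb of chromosome 18 it had 10 against 187 and 28 against 156. Input density of LY19Y646F in these bins was 0.809 and 0.714 times its autosomal median. As wholes, chromosomes 16 and 18 had 1278 against 1885 and 958 against 1325.

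Chromosomes 20 and 22 ran the other way. Chromosome 20 was covered to 30.5% in LY19WT and 40.1% in LY19Y646F, where its relative input density was 1.2. Chromosome 22 was covered to 21.7% and 33.9%, with relative input densities of 1.03 in LY19WT and 0.970 in LY19Y646F. Chromosome 21 was covered to 9.23% and 13%, chromosome 17 to 22% and 25.8%, and chromosome 19 to 13.2% and 14.4%. Chromosome X held 290 islands in LY19WT and 28 in LY19Y646F, with median input densities over these islands of 4.17 and 8.85 reads per kb. Of the 28 islands, 18 lay in the first 10 Mb, so these densities do not compare the same places. Within those 10 Mb the median was 4.20 reads per kb over 14 LY19WT islands and 8.52 over the 18 LY19Y646F islands.

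**Figure D2:**
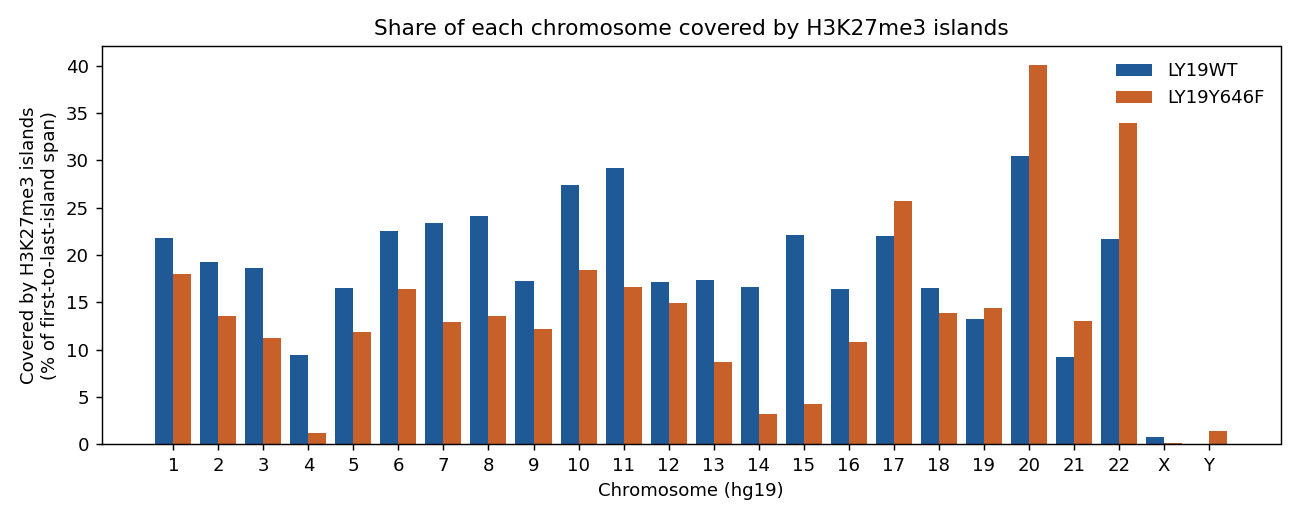
Percent of each chromosome's span covered by H3K27me3 islands in LY19WT (blue) and LY19Y646F (orange), with 1 bar per line. Chromosomes 4, 14 and 15 stand at 1.21%, 3.25% and 4.27% in LY19Y646F, while chromosomes 17, 19, 20, 21 and 22 are covered more in LY19Y646F than in LY19WT.

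The input libraries of the lines had different profiles along the genome. In LY19WT, input over islands was above the autosomal median from 140 to 190 Mb (1.28 times) and from 200 to 250 Mb (1.27) of chromosome 1, from 140 to 180 Mb of chromosome 6 (1.41), from 0 to 60 Mb of chromosome 7 (1.38) and from 20 to 120 Mb of chromosome 13 (1.39). The medians of LY19Y646F over the bins of these segments stood between 0.983 and 1.03, with single bins from 0.872 to 1.16. From 40 to 60 Mb of chromosome 6 LY19WT was high (1.31), and the median of LY19Y646F over these bins was 1.28. LY19Y646F was high only from 50 to 60 Mb and lay within 15% of its autosomal median from 40 to 50 Mb. LY19WT was low from 0 to 10 Mb of chromosome 1 (0.595) and from 70 to 80 Mb of chromosome 18 (0.439). In LY19Y646F, input was low from 50 to 110 Mb of chromosome 14 (0.762), from 60 to 110 Mb of chromosome 15 (0.758) and from 40 to 70 Mb of chromosome 16 (0.737). It was high from 50 to 80 Mb of chromosome 6 (1.52) and from 50 to 70 Mb of chromosome 18 (1.26). In 10 Mb bins, median coverage in LY19WT was 27.0% where its input was over 20% above the median and 18.2% where it lay within 15%, and LY19Y646F covered 14.9% and 11.1% of the same bins. In LY19Y646F coverage was 3.45% where its input was over 20% below the median, and LY19WT covered 16.9% of those bins. Coverage in LY19Y646F was 13% both where its input lay within 15% of the median and where it was over 20% above. LY19WT covered 19.5% and 13% of the same bins. The class over 20% above held 14 bins, with quartiles of LY19Y646F coverage of 3.52% and 33.1%. In 188 bins within 15% of the median in both lines, chosen after seeing the data, coverage was 19.1% in LY19WT and 14.2% in LY19Y646F.

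**Figure D3:**
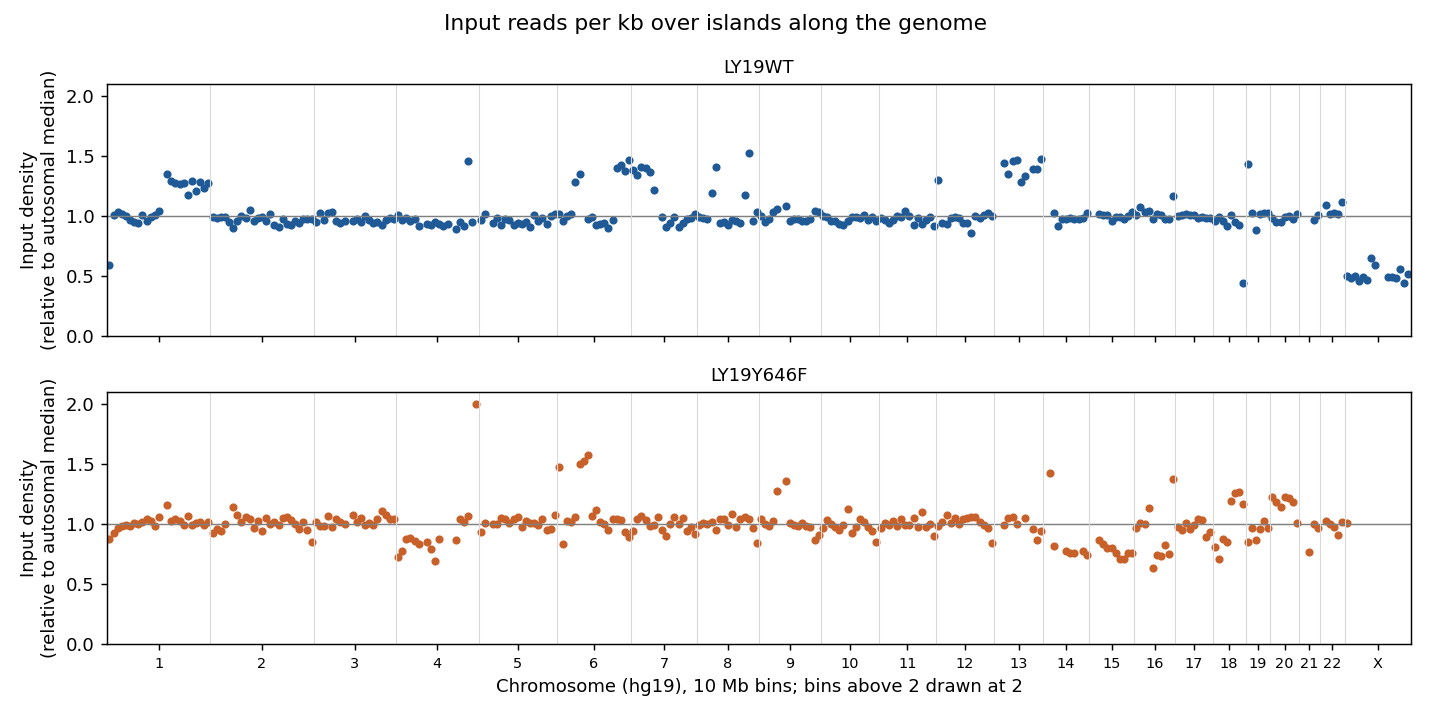
Median input reads per kb over islands in 10 Mb bins, relative to the autosomal median of the line, along chromosomes 1 to 22 and X, with 1 point per bin and values above 2 drawn at 2. LY19WT is high on parts of chromosomes 1, 6 and 7 and on chromosome 13, and LY19Y646F is low on chromosomes 14 and 15 and on much of chromosome 4.

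Islands of the lines overlapped more than random placement gave, but most of the covered length was found in 1 line alone. Of the LY19WT islands, 22735 (39.1%) overlapped a LY19Y646F island by at least 1 bp, against a mean of 25% and a maximum of 25.3% over 100 random placements on the same chromosomes. Of the LY19Y646F islands, 26811 (56.5%) overlapped a LY19WT island, against a mean of 30.0% and a maximum of 30.5%. Rotating all islands of a chromosome together gave means of 22.6% and 30.1%, with maxima of 24.5% and 33.2%. The shared length was 184.4 Mb, or 33.3% of the LY19WT and 48.1% of the LY19Y646F length, and the Jaccard index was 0.245. The product of the covered shares gave 71.8 Mb. LY19WT islands that overlapped LY19Y646F had a median width of 7.6 kb and a median authors' fold of 2.37, and those in LY19WT alone 5.0 kb and 2.23. In LY19Y646F the medians were 6.4 kb and 1.93 for overlapping islands, and 5.4 kb and 1.86 for the rest. By chromosome, the Jaccard index ran from 0.0377 on chromosome 4 to 0.457 on chromosome 20. When an overlap had to reach 50% of both islands, 14.4% of LY19WT and 17.6% of LY19Y646F islands counted as shared. With the LY19WT list cut by p-value to the covered length of LY19Y646F, the order of the lines turned. The shares were then 52.7% of LY19WT and 38.6% of LY19Y646F islands at 1 bp. The LY19Y646F list stayed whole, so the lists were not treated alike.

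Long stretches of the genome were covered by islands in 1 line and held few or none in the other. A stretch without islands can still hold the mark below the calling threshold. ChIP density over called islands had quartiles of 51.5 and 65.5 reads per kb in LY19WT, and of 38.8 and 45.1 in LY19Y646F. Of 30580 windows of 100 kb, 2676 were covered by at least 50 percentage points more in LY19WT and 740 in LY19Y646F, and 1397 were covered by at least 50% in both. Within bins of normal input in both lines the numbers were 1559 and 466. With the LY19WT list cut to the covered length of LY19Y646F, the windows made up 150.4 Mb and 108.4 Mb, against 267.6 and 74 Mb in the full lists. On chromosome 13, LY19WT islands covered 81.4% of the region from 101400001 to 103200000, and LY19Y646F islands covered 0.822%. On chromosome 8 the region from 122500001 to 123500000 was covered to 89.1% and 1.76%. On chromosome 6 the region from 146300001 to 147200000 was covered to 91.1% in LY19WT and held no LY19Y646F island. On chromosome 1 the region from 168400001 to 169100000 was covered to 95% and 8.29%. Input density of LY19WT was raised around these 4 regions, at 1.39, 1.52, 1.40 and 1.28 times its autosomal median. The region of chromosome 10 from 62600001 to 63500000 was covered to 79.8% and 5.47% at relative input densities of 0.960 and 1.13.

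The 5 named regions with the largest excess of coverage in LY19Y646F lay on chromosomes 6 and 20. From 6700001 to 7100000 on chromosome 6, coverage was 99% in LY19Y646F and 1.00% in LY19WT. From 4100001 to 4800000 it was 85% and 4.20%. From 5800001 to 6600000 it was 82.0% in LY19Y646F, with no LY19WT island. The region from 76400001 to 76600000 was covered to 74.6% in LY19Y646F, also with no LY19WT island. Relative input density of LY19Y646F was 1.57 around this last region and 1.47 around the other 3. On chromosome 20, the region from 59800001 to 60500000 was covered to 87.3% in LY19Y646F and 11% in LY19WT, at relative input densities of 1.01 and 1.02.

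**Figure D4:**
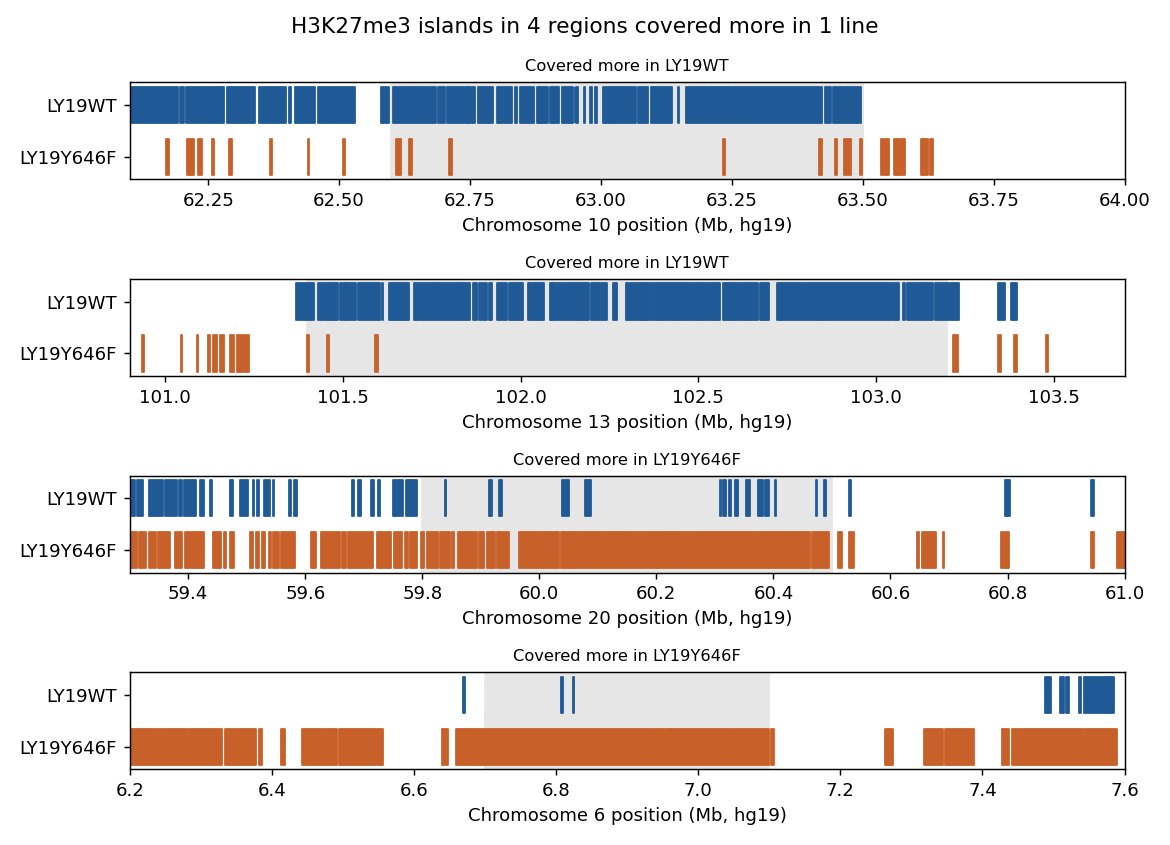
Islands of LY19WT (blue) and LY19Y646F (orange) as blocks along 4 regions, with position in Mb (hg19) on the horizontal axis and the named region shaded. LY19WT fills the chromosome 10 and chromosome 13 regions to 79.8% and 81.4%, and LY19Y646F fills the chromosome 20 and chromosome 6 regions to 87.3% and 99%.

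Where islands of the lines matched closely, enrichment over input was lower in LY19Y646F, although scaling by total ChIP reads in islands reversed the direction. Over 8368 pairs of islands that overlapped by at least 50% of both, the median authors' fold was 2.37 in LY19WT and 1.96 in LY19Y646F. The median log2 ratio of LY19Y646F to LY19WT was -0.27 when ChIP reads were scaled by input reads and the library ratio, with 72.7% of pairs lower, and turned to 0.55 when they were scaled by total ChIP reads in islands. That total was summed over lists of 383.6 and 554.6 Mb, so it falls with a shorter list as well as with lower levels at shared islands. The library ratio, like that total, moved every pair by the same amount, so the direction depends on the scaling chosen. No external scale such as a spike-in was used here. The log2 ratio scaled by input describes enrichment over input, not the amount of the mark.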

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

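The tests of DNA abundance, read threshold, mappability, sampled places and cell identity were chosen or divided by region only after the results were seen, as were the bins of normal input used in 1 test of the overlap, while the overlap at equal length was planned. Signals outside the main comparison came from chromosome Y and from the input libraries. LY19Y646F had 29 islands on chromosome Y, where LY19WT had 0. Median input over these 29 islands was 13.9 reads per kb, 1.65 times the autosomal median, and their median authors' fold was 1.49. LY19Y646F had 53 islands with input over 3 times the autosomal median, led by chromosome 17 from 22244401 to 22263000 at 1290 input reads per kb, and LY19WT had 23. Input in 10 Mb bins lay over 20% from the median in 1 line alone in 65 of 272 bins.

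Chromosomes 4, 14 and 15 carried few islands in LY19Y646F. On chromosomes 14 and 15, loss of the mark at an unchanged number of DNA copies was argued against by low input. Median input densities were at most 0.765 times that of the autosomes other than 4, 14 and 15 (95% bootstrap interval over islands 0.748 to 0.779, chromosome 14). The intervals given here hold the spread over islands of 1 input library, not a spread between libraries. Fewer DNA copies remain a candidate explanation. A threshold on ChIP reads that hides weaker islands cannot be told apart there, because the median folds, at least 1.21 times those of the other autosomes, rise by construction where input is low. On chromosome 4, loss of the mark from the whole chromosome at unchanged copies was argued against by an input density of 0.823 (0.782 to 0.854). Whether fewer copies were the whole cause cannot be told apart for the chromosome. From 150 to 170 Mb, at normal input and at least 0.95 in LY19Y646F, the ratio of islands was 0.102. Of 160 bins of other autosomes chosen in the same way, 3 were as low. From 150 to 180 Mb the ratio was 0.101 at a LY19Y646F input of 1.02 (0.960 to 1.08), over 51 LY19Y646F islands. Islands were thus few there without low LY19Y646F input. The stretch was picked after its input was seen, so that input cannot decide against fewer copies. From 170 to 180 Mb, LY19WT input was 1.46 times its autosomal median, outside the normal range. On the rest of chromosome 4 the ratio was 0.158 at an input of 0.781. A difference in the mark through EZH2 or clonal history stays open and was not tested.

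The input profiles of the lines differed along the genome. Mappability or base composition shared by both lines was argued against as the source by a Pearson r of 0.076 across 272 bins, which are not independent replicates. Sampling of different places was argued against by the matched islands, where the input ratio of LY19Y646F to LY19WT on chromosome 13 was 0.698 times that on the other autosomes. From autosomal bins, another cell population or a mislabelled sample cannot be told apart from clonal change within a line. The 65 bins that deviated in 1 line alone, against 1 that deviated the same way in both, could follow from any of them. Clonal change would leave so few shared bins only if a common parent line had few deviations, which is not known here. The sex chromosomes were not weighed here. Chromosome Y had 29 islands in LY19Y646F, at a median relative input of 1.65, and 0 in LY19WT. Relative input in the first 10 Mb of chromosome X was 1.01 in LY19Y646F and 0.499 in LY19WT. The LY19Y646F value rests on 18 of its 28 chromosome X islands and does not speak for the rest of that chromosome. The EZH2 difference itself was not tested as a source.

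The lists overlapped little, with a Jaccard index of 0.245. Different DNA copies were argued against as the whole cause, since the index was 0.251 in bins of normal input. The index was 0.225 when the LY19WT list was cut by p-value to the covered length of LY19Y646F. A longer LY19WT list was argued against as the whole cause only as far as that cut goes. The cut left the LY19Y646F list whole, and shared length fell from 184.4 to 140.7 Mb. The EZH2 difference, a different clonal history, variation between ChIP preparations and a threshold that hides weaker islands stay open and were not tested.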

How the results depend on the processing

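The FDR limits, joining, autosomes, overlap minima, equal length, window sizes and scalings were set before the data were examined, and normal-input bins and the removal of very high input were chosen after. Fewer islands and less covered length in LY19Y646F held under every alternative run for them. The ratio of islands was 0.797 at FDR 1e-05, 0.719 at 1e-10, 0.883 with islands joined across 5 kb, 0.860 in normal bins and 0.815 without very high input. The ratio of covered length was 0.678, 0.627, 0.692 on autosomes, 0.744 in normal bins and 0.690 without very high input. The ratio of median widths was 1.03 at 1e-10, 0.915 after joining and 1.04 in normal bins. Overlapping LY19WT islands made up 38.3% and 35.3% at the stricter FDRs, 25.9% and 14.4% at 50% of 1 and of both islands, 52.7% at equal length and 41.1% in normal bins. For LY19Y646F the last 4 were 44.0%, 17.6%, 38.6% and 55.5%, so the order of the lines turned at equal length. The Jaccard index was 0.241 and 0.225 at the stricter FDRs, 0.245 on autosomes, 0.225 at equal length, 0.251 in normal bins and 0.245 without very high input. Windows higher in LY19Y646F made up 21 Mb at 500 kb, 108.4 Mb at equal length and 46.6 Mb in normal bins, against 74 Mb as reported. Those higher in LY19WT made up 178 Mb at 500 kb, 150.4 Mb at equal length and 155.9 Mb in normal bins, against 267.6 Mb. The paired log2 ratio reversed to 0.55 by total reads in islands and was -0.50 by input counts, against -0.27. The total sums over lists of unequal length, so the reversal can follow from list length and is no evidence of higher levels at shared islands. The library ratio moves every pair alike too, so the direction rests on the scaling chosen. No paired analysis was possible because each list was called on merged replicates, and no replicate could be left out. Promoter, gene list and gene body alternatives were not run for lack of an annotation on hg19. The effect of depth on weak islands was not tested.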

Other observations

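The tests of chromosome ends were chosen only after coverage and input along the chromosomes had been seen. In the last 10 Mb of the autosomes, coverage relative to the rest was higher in LY19Y646F than in LY19WT. The last 10 Mb of the 22 autosomes was covered to 25% in LY19Y646F and 22.5% in LY19WT, while the rest was covered to 12.8% and 19.6%. The end was covered more than the rest on 20 autosomes in LY19Y646F and on 12 in LY19WT. On chromosome 9 the end was covered to 33.8% in LY19Y646F and 18.6% in LY19WT, and the rest to 10.6% and 17.1%. On chromosome 7 the end was covered to 32.6% and 17.6%, and on chromosome 12 to 24.2% and 7.87%.

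A shift of covered length towards the last 10 Mb in LY19Y646F is a hypothesis from these data. The ratio of end to rest was higher in LY19Y646F on 17 of 22 autosomes, the smallest number set as the limit for this test, and lower on chromosomes 1, 4, 6, 15 and 16. Of the 18 autosomes whose end had input within 20% of the rest in both lines, 16 had the higher ratio in LY19Y646F. Median input density at the ends was 0.924 times that of the rest in LY19Y646F and 1.01 times in LY19WT, so a difference in library composition could also raise enrichment there. That was not tested, since no genome sequence was used here. At the other end the test was not decisive: the first 10 Mb relative to the rest was covered more in LY19Y646F on 13 of 18 autosomes, below the limit set, and 1 of these, chromosome 21, had no LY19WT island there.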
